A study of Macaca mulatta with 79 samples.

How the data were processed

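The log2 expression values were used as deposited, as 1 table of 46552 probe sets by 79 arrays, with values from -0.21 to 17.1. The submitters' notes name RMA, affy and limma without versions or settings. The RNA had been labelled by a 3' in vitro transcription method and hybridised to Affymetrix rhesus arrays. In the values themselves, the mean of each probe set within each of the 6 batches equalled its mean over all arrays to within 5.7e-09, so each batch had been centred without regard to the groups it held. Centring of that kind takes part of any group difference out of a batch with unequal groups, and a batch term in the model absorbs it. Levels are therefore given as batch-adjusted values, meaning the deposited value less the fitted batch term. The single array of batch 10 (HC blood 19) carries no information under this model, which leaves 22 informative HC blood arrays.

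The labels give the arm, tissue, animal, batch, day after HCT and sex of each array. They name 35 animals, of which 24 were HC, 4 Auto and 10 GVHD, with 3 animals in 2 arms. The series text counts 13 transplanted animals where the labels give 14, and 1 animal carries conflicting sex labels. Batch 7 held 39 arrays (20 HC, 19 GVHD), batch 9 held 20 (6 HC, 12 Auto, 2 GVHD) and batch 8 held 12 (9 HC, 3 GVHD). Batch 2 held 5 arrays (4 HC, 1 GVHD), batch 5 held 2 HC arrays, and all Auto arrays lay in batch 9. The highest correlation between any pair of arrays was 0.994, and 0 pairs were identical.

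Of the probe sets, 22357 had exactly 1 gene symbol, 308 had several, 23887 had none and 121 were controls. For each gene the probe set with the highest mean over all arrays was taken, which gave 12901 genes, 5633 of them with more than 1 probe set. Among named genes with more than 1 probe set, 20 of 129 pairs of gene and comparison had a probe set with the opposite sign. Positions are those of the rhesus genome build MMU8v2.0 (telomere to telomere), found for 537 of 545 named genes and list members. CD3E, PRF1, PDCD1 and ALB had no such probe set and were not analysed here.

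Linear models were fitted in limma to all 79 arrays with 9 group means, batch as a fixed term and the animal as a random block, for which duplicateCorrelation gave a correlation of 0.26. The fit had 65 residual degrees of freedom, and empirical Bayes added 3.36 prior degrees of freedom. Each comparison is a contrast of this fit, tested by the two-sided moderated statistic and adjusted by Benjamini-Hochberg over the 12901 genes, and a gene was called at an adjusted p under 0.05. The n behind an effect is the number of informative arrays in each group. The difference between tissues in the GVHD effect was tested as an interaction. Numbers in the array titles do not pair animals across arms. In 9 comparisons between arms 0 pairs of arrays with a shared number came from 1 animal, and in GVHD and HC blood their mean correlation was 0.04. In liver and blood of HC 1 of 10 such pairs came from 1 animal. Auto arrays with a shared number came from 1 animal, with correlations between tissues from 0.38 to 0.63.

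Named genes followed a rule written before the data were examined, as were the comparisons, the lists and most alternatives. A fixed set of T cell genes could be named in every comparison, as could the 6 highest and 6 lowest called genes by fold change. In a list that was called or discussed, up to 4 called members and up to 2 that did not pass could be named. Gene lists were tested with camera on data whitened by the animal correlation, with a preset inter-gene correlation of 0.01, adjusted over the 33 lists of a comparison, and again with an estimated correlation. Of 156 calls over the 13 comparisons, 19 held with the estimated correlation. They were cytotoxic and type 1 genes in GVHD against Auto blood, p53 response in GVHD against Auto liver and lungs, and p53 response in Auto against HC liver and lungs. Auto against HC liver also kept cell cycle, type 17, regulatory T cell, STAT5 and cholesterol genes. HC liver against blood kept type 1, naive, residency, immediate early and NK genes, and HC lungs against blood kept naive, residency and heat shock genes. For each of the 156 the median, the mean and the test had 1 sign.

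The lists, with measured genes out of all symbols, were cell cycle (28 of 45), cytotoxic effector (17 of 20), type 1 helper and interferon gamma axis (10 of 16), type 2 helper (10 of 12), type 17 and type 22 helper (11 of 15), and regulatory T cell (11 of 12). They also covered inhibitory receptor and exhaustion (14 of 15), activation and costimulation (13 of 18), naive and central memory (13 of 20), tissue residency (16 of 19), tissue egress and recirculation (7 of 11), chemokine receptors and integrins (19 of 24) and chemokines (13 of 16). Further lists were type I interferon response (28 of 38), interferon gamma response and antigen processing (18 of 26), STAT5 and cytokine signalling feedback (17 of 20), T cell receptor signalling (15 of 25), immediate early and dissociation stress (14 of 21), heat shock and unfolded protein response (14 of 22), glycolysis (15 of 20), oxidative phosphorylation (24 of 39), cholesterol and fatty acid synthesis (14 of 22), p53 response (18 of 20) and cytosolic ribosomal proteins (20 of 46). Marker lists covered B cells (10 of 18), plasma cells (8 of 12), NK cells (12 of 16), monocytes and macrophages (21 of 25), neutrophils (10 of 17), hepatocytes (18 of 24), lung epithelium (16 of 18), endothelium and stroma (13 of 18), and erythroid cells and platelets (10 of 17). Gamma delta and innate-like T cell genes (4 of 12) were too few to test, and 0 of 11 sex-linked genes were measured. Some genes stand in several lists, for example ENTPD1, CTLA4 and TIGIT in the regulatory T cell and inhibitory receptor lists.

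In simulated values with the design and batch centring of the series, the fit called 82.1% and 94.0% of genes changed by 0.5 and 1 on the log2 scale in GVHD against HC liver, and 44.8% and 88.1% in Auto against HC blood. Of unchanged genes it called 8 in each. Without a batch term it called 3 in GVHD against HC liver and 37 in Auto against HC blood, where it found 55.2% of changes of 0.5. On random lists, not co-expressed ones, camera gave p under 0.05 for 2.5%. Alternatives covered the batch term, the animal block, a title-number block, single tissues and batches, the choice and level of probe sets, quantile normalization, the prior, sex, day 8 alone, animals in 2 arms, and each Auto animal left out in turn. A call counted as reversed where its sign changed. Calculations used R 4.3.3 with limma 3.58.1 and statmod 1.5.0.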

Results

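The series holds 79 arrays of T cells from rhesus macaques, sorted by flow cytometry as cells that carry CD3, the signalling part of the T cell receptor, and lack CD20, a B cell surface protein. Hematopoietic cell transplantation (HCT) replaces the blood-forming cells of a conditioned animal. In the GVHD arm the graft came from another animal, and donor T cells can then attack the recipient's tissues, which is graft-versus-host disease. In the Auto arm the animal received its own cells. The healthy control arm (HC) was not transplanted. T cells came from blood, liver or lungs, so that 3 arms and 3 tissues made 9 groups. HC held 23 blood, 10 liver and 9 lung arrays, Auto held 4 arrays of each tissue, and GVHD held 9 blood, 9 liver and 7 lung arrays. The Auto samples were taken on day 8 after HCT and the GVHD samples between days 7 and 12. Array medians lay between 5.52 and 5.66 on the log2 scale, and the number of arrays is among the limits on the precision. The first principal component of the batch-adjusted values held 33.1% of the variance and the second 19.9%.

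**Figure D1:**
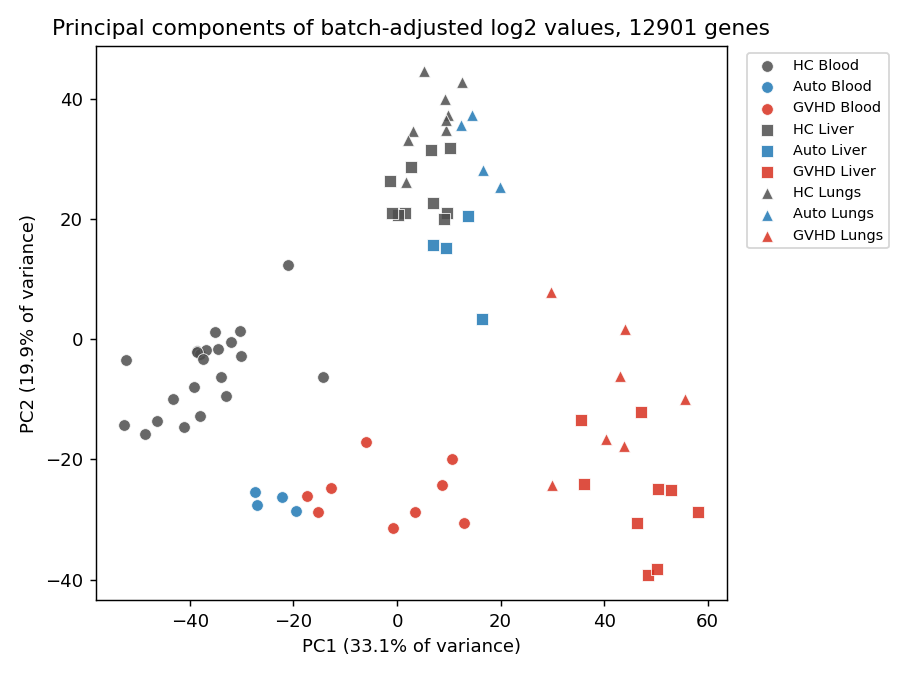
Each point is 1 array, placed by its first (33.1% of variance) and second (19.9%) principal component of the batch-adjusted log2 values, with the arm shown by colour and the tissue by shape. The GVHD liver and lung arrays lie to the right of all others.

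All folds below are log2 fold changes with their standard errors (SE) from 1 limma fit over 12901 genes, and genes were called at an adjusted p under 0.05. A number of list members that rose or fell counts called members. Probe sets had a median level of 5.60, and the fold of a gene against a group near or under that level depends on the background signal.

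The question of the comparison with HC is how T cells of animals with GVHD differ from those of untransplanted animals. In blood (9 GVHD arrays, 22 informative HC arrays), T cells of the GVHD arm carried more transcript of LAG3, an inhibitory receptor that binds MHC class II (chromosome 11, 7736697 to 7742696, 3.26 ± 0.20), and of MKI67, a nuclear protein of cycling cells (chromosome 9, 140137853 to 140169149, 2.11 ± 0.21). GZMB, a granzyme with which cytotoxic cells kill their targets, rose by 1.42 ± 0.19, and the cytokine gene IFNG by 1.68 ± 0.32. CXCR6, a chemokine receptor of tissue T cells, rose by 1.38 ± 0.26. TCF7, a transcription factor of naive and memory T cells, fell by 0.61 ± 0.18. CD8A (0.41 ± 0.08) and CD8B (0.57 ± 0.16) rose, while CD4 (-0.14 ± 0.13), FOXP3 (-0.03 ± 0.10) and IL17A (-0.14 ± 0.28) did not pass the test. The highest folds belonged to HBG2, a globin chain (4.38 ± 0.65), the chemokine CCL23 (3.77 ± 0.37), the calprotectin subunits S100A9 (3.61 ± 0.65) and S100A8 (3.59 ± 0.59), and IFI27, an interferon-induced gene (3.32 ± 0.31). The lowest were SOX4, a transcription factor (-2.60 ± 0.36), MAMDC2 (-2.25 ± 0.25), MAML3, a coactivator of Notch signalling (-2.25 ± 0.26), and JAKMIP2 (-2.11 ± 0.22).

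Of 28 measured cell cycle genes in blood, 26 rose and 1 fell, over all genes as well as adjusted over the list alone, with a median of 1.5 (camera adjusted p = 5.17e-18, and adjusted p = 0.126 with an estimated correlation). TYMS, which makes thymidylate for DNA synthesis, rose by 2.59 ± 0.25 and CCNB2, a mitotic cyclin, by 2.47 ± 0.24. Among 28 type I interferon response genes 21 rose and 1 fell, and the same numbers passed when adjusted over the list alone (median 0.89, adjusted p = 3.62e-10, and adjusted p = 0.126 with an estimated correlation). ISG15 rose by 1.90 ± 0.17 and MX2 by 1.73 ± 0.20. Of 18 genes of the interferon gamma response and antigen processing, 11 rose and 2 fell, as they did adjusted over the list alone (median 0.39, adjusted p = 3.08e-04, and adjusted p = 0.126 with an estimated correlation). IRF8 rose by 2.18 ± 0.22, and the class II gene MAMU-DRA fell by 1.4 ± 0.42.

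Cytotoxic effector genes rose in 10 of 17 cases, and none fell; adjusted over the list alone the number was also 10 (median 0.71, adjusted p = 8.9e-04, and adjusted p = 0.214 with an estimated correlation). GNLY, which encodes granulysin, rose by 1.57 ± 0.18 and FASLG, a death ligand, by 1.19 ± 0.28. In the list of the type 1 helper and interferon gamma axis 5 of 10 genes rose, or 6 adjusted over the list alone (median 0.69, adjusted p = 0.0035, and adjusted p = 0.140 with an estimated correlation), led by the receptor chain IL12RB2 (2.39 ± 0.26). Inhibitory receptor and exhaustion genes rose in 7 of 14 cases and fell in 1, with the same numbers adjusted over the list alone (median 0.48, adjusted p = 0.0058, and adjusted p = 0.126 with an estimated correlation). Besides LAG3, HAVCR2, which encodes TIM-3, rose by 2.30 ± 0.22 and CTLA4 by 1.05 ± 0.23. Of 11 regulatory T cell genes 8 rose and 1 fell, or 8 and 2 adjusted over the list alone (median 0.71, adjusted p = 0.0207, and adjusted p = 0.213 with an estimated correlation). The members that rose included ENTPD1, an ectonucleotidase (2.30 ± 0.22), and IL2RA (1.09 ± 0.16), which activated T cells also express. Naive and central memory genes fell in 8 of 13 cases, or 9 adjusted over the list alone (median -0.40, adjusted p = 3.39e-04, and adjusted p = 0.126 with an estimated correlation). Members that passed included KLF7 (-1.20 ± 0.18) and PIK3IP1, an inhibitor of phosphoinositide kinase (-1.07 ± 0.16).

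Glycolysis genes rose in 10 of 15 cases, also adjusted over the list alone (median 0.42, adjusted p = 2.09e-05, and adjusted p = 0.126 with an estimated correlation). Oxidative phosphorylation genes rose in 19 of 24 cases, or 19 with 1 that fell adjusted over the list alone (median 0.29, adjusted p = 8.79e-07, and adjusted p = 0.126 with an estimated correlation). Of 14 heat shock and unfolded protein response genes 7 rose and 1 fell, the same adjusted over the list alone (median 0.34, adjusted p = 0.0117, and adjusted p = 0.214 with an estimated correlation). Cytosolic ribosomal protein genes fell in 14 of 20 cases and rose in 2, or 15 and 2 adjusted over the list alone (median -0.18, adjusted p = 7.69e-05, and adjusted p = 0.126 with an estimated correlation).

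Neutrophil markers rose in 9 of 10 cases, also adjusted over the list alone (median 1.32, adjusted p = 0.0032, and adjusted p = 0.384 with an estimated correlation). LCN2, a granule protein, stood at 3.15 ± 0.49 and MMP8 at 2.52 ± 0.46. Erythroid and platelet markers rose in 9 of 10 cases, also adjusted over the list alone (median 0.94, adjusted p = 0.0022, and adjusted p = 0.214 with an estimated correlation). The platelet chemokine PPBP stood at 3.04 ± 0.63 and HBB at 1.25 ± 0.35. The GVHD blood arrays 1, 4, 6 and 7 had means over the neutrophil markers of 8.13, 8.81, 8.90 and 6.48, above every HC blood array. Without them, and without a lung array of the same kind, the median of the neutrophil list was 0.14 (adjusted p = 0.805) and that of the erythroid and platelet list 0.47 (adjusted p = 0.198), while S100A9 stood at 2.79 (adjusted p = 0.0040). The cell cycle list then had a median of 1.62, the type I interferon list 0.89, the cytotoxic list 0.54 and the inhibitory receptor list 0.42, each still called.

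In blood 5079 of 12901 genes were called, 2902 higher and 2177 lower in GVHD, and 313 and 148 of them changed at least 2-fold. Within batch 7 alone (7 GVHD and 12 HC arrays) 4135 genes were called, LAG3 stood at 3.32 and MKI67 at 1.76, and TCF7 (-0.53, adjusted p = 0.103) was no longer called. SOX4 had 4 probe sets, with other folds between -1.80 and 0.17. The second probe set of MAML3 stood at -0.30, the others of MKI67 at 0.82 and 0.88, and that of CD8B at 0.34.

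In liver (9 GVHD and 10 HC arrays) the largest rises were in TIMD4, a receptor for phosphatidylserine (4.30 ± 0.32), the transcription factor gene ZBED2 (4.13 ± 0.44), CTHRC1 (4.03 ± 0.38), OIP5, which helps to build centromeres (4.03 ± 0.26), the protease inhibitor gene SERPINE2 (3.96 ± 0.39) and UBE2K, a ubiquitin-conjugating enzyme (3.95 ± 0.30). The largest falls included SLC40A1, the iron exporter (-4.24 ± 0.38), SELENOP, a secreted selenium carrier (-3.58 ± 0.58), and JAKMIP2 (-3.46 ± 0.27). KLRF1, an activating NK receptor (-3.22 ± 0.35), and ZBTB16, a transcription factor of innate-like T cells (-3.07 ± 0.31), fell too. MKI67 rose by 2.96 ± 0.25, GZMB by 0.88 ± 0.23, CD8A by 0.29 ± 0.09 and CD8B by 0.66 ± 0.19. TCF7 fell by 1.86 ± 0.22, IL17A by 1.04 ± 0.34 and CD69, an early activation and retention antigen, by 0.49 ± 0.20. Other probe sets gave 1.57 and 1.75 for MKI67, -1.92 and -1.13 for TCF7, and -2.02 for SELENOP. IL17A averaged 5.65 in HC and 4.60 in GVHD liver. IFNG (0.52 ± 0.39), TBX21 (0.34 ± 0.26), FOXP3 (0.07 ± 0.11), CCR7 (-0.35 ± 0.27), ITGAE (-0.25 ± 0.16) and CXCR6 (0.07 ± 0.31) did not pass.

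Cell cycle genes of liver T cells rose in 26 of 28 cases and 1 fell, also adjusted over the list alone (median 2.63, adjusted p = 4.49e-23, and adjusted p = 0.0742 with an estimated correlation). MELK rose by 3.32 ± 0.27 and KIF23, a kinesin of cell division, by 3.25 ± 0.26. Oxidative phosphorylation genes rose in 21 of 24 cases, also adjusted over the list alone (median 0.51, adjusted p = 1.5e-09, and adjusted p = 0.0742 with an estimated correlation). Glycolysis genes rose in 11 of 15 and fell in 2, the same adjusted over the list alone (median 0.68, adjusted p = 4.73e-05, and adjusted p = 0.0742 with an estimated correlation). HK2, a hexokinase, rose by 1.91 ± 0.27 and PKM, pyruvate kinase, by 1.39 ± 0.10. Of the inhibitory receptor and exhaustion genes 8 of 14 rose and 3 fell, also adjusted over the list alone (median 0.74, adjusted p = 0.0200, and adjusted p = 0.276 with an estimated correlation). HAVCR2 stood at 3.94 ± 0.26, CTLA4 at 3.67 ± 0.28 and LAG3 at 3.01 ± 0.24. In the heat shock and unfolded protein response list 9 of 14 rose and 4 fell, also adjusted over the list alone (median 0.55, adjusted p = 0.0171, and adjusted p = 0.281 with an estimated correlation). SDF2L1, of the endoplasmic reticulum, rose by 1.28 ± 0.11, and the chaperone gene DNAJB1 fell by 1.14 ± 0.41. Immediate early and dissociation stress genes fell in 11 of 14 cases, also adjusted over the list alone (median -1.25, adjusted p = 2.97e-04, and adjusted p = 0.281 with an estimated correlation). FOS stood at -2.54 ± 0.51 and JUNB at -1.79 ± 0.22. Naive and central memory genes fell in 8 of 13 and rose in 1, also adjusted over the list alone (median -0.40, adjusted p = 0.0041, and adjusted p = 0.281 with an estimated correlation). Ribosomal protein genes fell in 12 of 20 and rose in 1, or 14 and 1 adjusted over the list alone (median -0.24, adjusted p = 3.71e-04, and adjusted p = 0.276 with an estimated correlation).

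Among markers of other cells in liver, 7 of 12 NK cell markers fell and 2 rose (median -0.71, adjusted p = 0.197), and 8 of 21 monocyte and macrophage markers fell and 4 rose (median -0.50, adjusted p = 0.272); neither list was called. Of 4 measured gamma delta and innate-like T cell genes, too few for the list test, 2 fell. In liver 5927 genes were called, 3145 higher and 2782 lower, with 588 and 450 at least 2-fold. Batch 7 alone (7 GVHD and 4 HC arrays) gave 4773 genes, with a cell cycle median of 2.52 and HAVCR2 at 4.16.

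In lungs (7 GVHD and 9 HC arrays) OIP5 (3.72 ± 0.28), SERPINE2 (3.69 ± 0.42), UBE2K (3.68 ± 0.33), LAG3 (3.58 ± 0.26), CCNB2 (3.58 ± 0.30) and TYMS (3.45 ± 0.32) rose most. JAKMIP2 (-3.50 ± 0.29), ARMCX4 (-3.08 ± 0.26), SMAD7, an inhibitor of TGF-beta signalling (-2.90 ± 0.27), IL1B (-2.84 ± 0.63), SLC40A1 (-2.74 ± 0.40) and LUM, a matrix proteoglycan (-2.69 ± 0.34), fell most. MKI67 rose by 2.98 ± 0.27, CD8B by 0.97 ± 0.20, CD8A by 0.50 ± 0.10, IFNG by 1.03 ± 0.42 and ITGAE, an integrin chain that binds epithelial E-cadherin, by 0.43 ± 0.17. TCF7 fell by 0.97 ± 0.23 and the lymph node homing receptor CCR7 by 0.73 ± 0.29. GZMB (0.44 ± 0.24), TBX21 (-0.46 ± 0.28), FOXP3 (0.21 ± 0.12), IL17A (-0.70 ± 0.36), CXCR6 (0.55 ± 0.34) and CD4 (-0.03 ± 0.16) did not pass.

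The cell cycle list had 26 of 28 members higher and 1 lower in GVHD lungs, or 26 and 2 adjusted over the list alone (median 2.24, adjusted p = 2.66e-22, and adjusted p = 0.111 with an estimated correlation). Inhibitory receptor and exhaustion genes rose in 10 of 14 cases and fell in 1, also adjusted over the list alone (median 0.91, adjusted p = 0.0021, and adjusted p = 0.111 with an estimated correlation). HAVCR2 stood at 3.07 ± 0.28, ENTPD1 at 2.83 ± 0.28 and CTLA4 at 2.27 ± 0.30. Type I interferon response genes rose in 19 of 28, or 19 with 1 that fell adjusted over the list alone (median 0.58, adjusted p = 6.76e-05, and adjusted p = 0.343 with an estimated correlation). IFI27 rose by 3.0 ± 0.40. Oxidative phosphorylation genes rose in 21 of 24 cases, or 21 with 1 that fell adjusted over the list alone (median 0.44, adjusted p = 2.84e-09, and adjusted p = 0.111 with an estimated correlation). Glycolysis genes rose in 11 of 15 and fell in 1, also adjusted over the list alone (median 0.47, adjusted p = 0.0017, and adjusted p = 0.219 with an estimated correlation). Immediate early genes fell in 7 of 14, or 8 adjusted over the list alone (median -0.91, adjusted p = 0.0027, and adjusted p = 0.343 with an estimated correlation). Naive and central memory genes fell in 7 of 13 and rose in 1, also adjusted over the list alone (median -0.45, adjusted p = 0.0160, and adjusted p = 0.343 with an estimated correlation). Ribosomal protein genes fell in 10 of 20 and rose in 1, also adjusted over the list alone (median -0.17, adjusted p = 0.0027, and adjusted p = 0.343 with an estimated correlation). In lungs none of 10 neutrophil markers passed (median 0.45, adjusted p = 0.905), and 3 of 13 endothelial and stromal markers fell (median -0.21, adjusted p = 0.0911). The comparison called 5158 genes, 2827 higher and 2331 lower, with 417 and 369 at least 2-fold. Batch 7 alone (5 GVHD and 4 HC arrays) gave 3771 genes and a cell cycle median of 2.08, and CCR7 was not called there (-0.78, adjusted p = 0.132). Other probe sets gave 0.07 to 3.13 for TYMS, -2.44 to 0.04 for LUM, -0.96 to -0.43 for TCF7, 1.5 and 1.61 for MKI67, and 0.62 for CD8B.

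**Figure D2:**
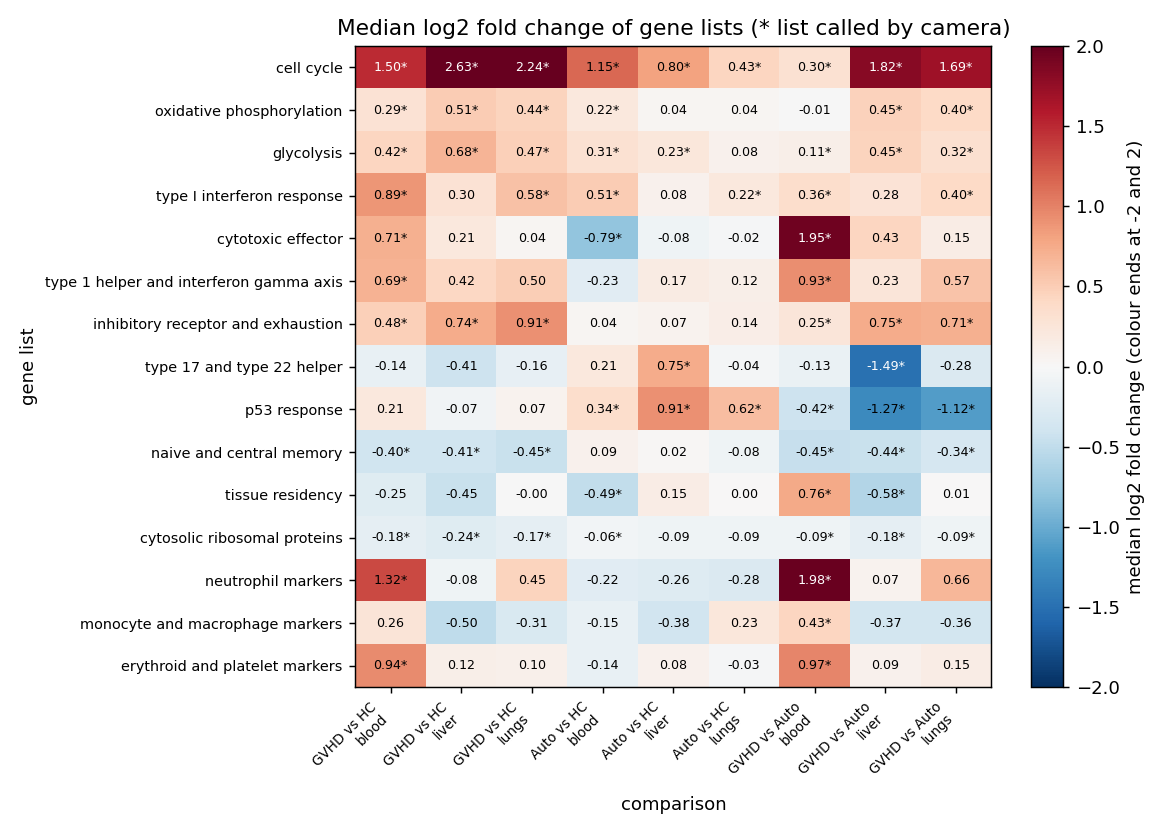
Median log2 fold change of 15 gene lists (vertical axis) in 9 comparisons of the arms (horizontal axis), with colour for the median and a star for lists called by camera. The cell cycle list had medians of 1.5, 2.63 and 2.24 in GVHD against HC, and the p53 response list 0.91 and 0.62 in Auto against HC liver and lungs.

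The Auto arm shows what transplantation with the animal's own cells leaves in T cells at day 8. In blood (4 Auto and 22 informative HC arrays) MKI67 rose by 1.82 ± 0.37, the lactate transporter gene SLC16A1 by 2.41 ± 0.45, UHRF1, which maintains DNA methylation, by 2.19 ± 0.42 and the cytokine feedback genes SOCS2 and CISH by 2.36 ± 0.53 and 2.32 ± 0.44. FOXP3, the transcription factor of regulatory T cells, rose by 0.86 ± 0.17. GZMB fell by 1.32 ± 0.33, CD69 by 1.01 ± 0.30 and TBX21, the transcription factor of type 1 helper cells, by 1.15 ± 0.39. The largest falls were in CLSPN (-3.06 ± 0.58), ZEB2, a transcription factor of effector T cells (-2.77 ± 0.44), RGS2 (-2.53 ± 0.68) and EGR2 (-2.43 ± 0.62). CLSPN, RGS2 and EGR2 each had a second probe set, at 0.22, 0.08 and -0.07. Other probe sets gave -0.12 to 2.20 for SLC16A1, 0.14 and 0.72 for MKI67, and 0.05 to 1.94 for TYMS. CD4 (0.46 ± 0.22), CD8A (-0.22 ± 0.14), IFNG (-0.77 ± 0.57), CCR7 (0.47 ± 0.40) and TCF7 (0.05 ± 0.32) did not pass.

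Cell cycle genes rose in 20 of 28 cases in Auto blood, or 23 adjusted over the list alone (median 1.15, adjusted p = 3.82e-14, and adjusted p = 0.195 with an estimated correlation). TYMS stood at 2.20 ± 0.45 and TOP2A, a DNA topoisomerase, at 2.09 ± 0.44. Cytotoxic effector genes fell in 9 of 17 and rose in 1, also adjusted over the list alone (median -0.79, adjusted p = 3.55e-07, and adjusted p = 0.150 with an estimated correlation). Members that passed included GZMH (-2.08 ± 0.50) and CST7 (-1.70 ± 0.26). The NK cell markers fell in 2 of 12 cases and rose in 1, or 3 and 2 adjusted over the list alone (median -0.74, adjusted p = 0.0473, and adjusted p = 0.506 with an estimated correlation). Without Auto animal 4 the NK list was not called (-0.88, adjusted p = 0.0879). Of 17 STAT5 and cytokine signalling feedback genes 5 rose, also adjusted over the list alone (median 0.18, adjusted p = 0.0212, and adjusted p = 0.322 with an estimated correlation); without Auto animal 1 the adjusted p was 0.0522. Regulatory T cell genes rose in 4 of 11, or 6 adjusted over the list alone (median 0.48, adjusted p = 0.0122, and adjusted p = 0.203 with an estimated correlation). The type I interferon list had 9 of 28 members higher, or 12 with 1 lower adjusted over the list alone (median 0.51, adjusted p = 9.02e-05, and adjusted p = 0.338 with an estimated correlation). Of 18 p53 response genes 8 rose, or 9 with 1 that fell adjusted over the list alone (median 0.34, adjusted p = 1.12e-04, and adjusted p = 0.160 with an estimated correlation). ZMAT3 stood at 1.4 ± 0.24 and BAX, which promotes apoptosis, at 1.01 ± 0.18; without a batch term the list was not called (0.20, adjusted p = 0.938).

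Tissue residency genes fell in 5 of 16 cases in Auto blood, or 5 with 1 that rose adjusted over the list alone (median -0.49, adjusted p = 2.54e-04, and adjusted p = 0.150 with an estimated correlation). Immediate early genes fell in 5 of 14, also adjusted over the list alone (median -0.54, adjusted p = 0.0027, and adjusted p = 0.338 with an estimated correlation), but within batch 9 the median was -0.10 (adjusted p = 0.0830). Chemokine genes fell in 2 of 13, also adjusted over the list alone (median -0.44, adjusted p = 0.0191, and adjusted p = 0.338 with an estimated correlation), namely CCL5 (-1.93 ± 0.41) and CCL4L1 (-1.59 ± 0.49). CCL4L1 was not called without Auto animals 2, 3 or 4 (adjusted p = 0.0703, 0.0604 and 0.0799). Oxidative phosphorylation genes rose in 10 of 24, or 11 adjusted over the list alone (median 0.22, adjusted p = 2.64e-07, and adjusted p = 0.160 with an estimated correlation). Glycolysis genes rose in 5 of 15, or 9 adjusted over the list alone (median 0.31, adjusted p = 0.0031, and adjusted p = 0.203 with an estimated correlation). Cholesterol and fatty acid synthesis genes rose in 4 of 14, or 5 adjusted over the list alone (median 0.20, adjusted p = 0.0476, and adjusted p = 0.322 with an estimated correlation). Without Auto animals 1 and 4 in turn the adjusted p was 0.104 and 0.0578. The ribosomal protein list was called lower with 0 of 20 members past the test (median -0.06, adjusted p = 0.0256, and adjusted p = 0.432 with an estimated correlation).

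The comparison in blood called 1528 genes, 1202 higher and 326 lower, with 184 and 86 at least 2-fold. Fitted on blood alone it called 144 genes, 124 higher and 20 lower, and without a batch term 2294. Without Auto animal 3 the count was 992. All Auto arrays lay in batch 9, which held 2 HC arrays of each tissue; within that batch 595 genes were called. There the medians were 1.16 for cell cycle and -1.24 for cytotoxic genes, MKI67 stood at 1.67 and ZEB2 at -2.72. FOXP3 (0.71, adjusted p = 0.0955), GZMB (-1.06, adjusted p = 0.302), TBX21 (-1.34, adjusted p = 0.129), CD69 (-0.12, adjusted p = 0.788) and GZMH (-2.48, adjusted p = 0.124) were not called within it. Leaving out Auto animals 2, 3 or 4 also ended the call of TBX21 (adjusted p = 0.136, 0.0797 and 0.131), and leaving out animal 2 that of CD69 (adjusted p = 0.0575).

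In liver (4 Auto and 10 HC arrays) the p53 response list stood out from the 33 lists tested. Of its 18 members 8 rose, or 11 adjusted over the list alone, with a median of 0.91 (adjusted p = 1.88e-32, and 1.33e-07 as the adjusted p with an estimated correlation). DDB2, a sensor of damaged DNA (chromosome 14, 18360392 to 18386776), rose by 1.91 ± 0.15, ZMAT3 by 1.96 ± 0.25, MDM2, the ubiquitin ligase of p53, by 1.77 ± 0.30 and BAX by 1.75 ± 0.18. Within batch 9 alone they were also called, with DDB2 at 1.93 and MDM2 at 2.06. Of 11 type 17 and type 22 helper genes 4 rose, also adjusted over the list alone (median 0.75, adjusted p = 2.86e-10, and 9.03e-04 as the adjusted p with an estimated correlation): the cytokine genes IL17A (chromosome 4, 130122960 to 130126607, 2.05 ± 0.51), IL22 (1.92 ± 0.45), CSF2 (1.34 ± 0.27) and IL26 (1.08 ± 0.22). IL17A was not called without Auto animal 2 (1.30, adjusted p = 0.423) or animal 4 (1.59, adjusted p = 0.297), nor was IL22 (1.57, adjusted p = 0.206, and 1.51, adjusted p = 0.198), nor IL26 without animal 2 (0.68, adjusted p = 0.206). Within batch 9 IL17A stood at 1.66 (adjusted p = 0.544) and IL22 at 1.33 (adjusted p = 0.470), and CSF2 (adjusted p = 0.127) and IL26 (adjusted p = 0.499) were not called either. The list itself had a median of 0.56 there (adjusted p = 0.0031).

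Cholesterol and fatty acid synthesis genes of Auto liver rose in 1 of 14 cases over all genes, FDFT1 (0.42 ± 0.10), and in 6 adjusted over the list alone (median 0.35, adjusted p = 2.51e-08, and 6.13e-04 as the adjusted p with an estimated correlation). Cell cycle genes rose in 5 of 28, or 16 adjusted over the list alone (median 0.80, adjusted p = 3.44e-21, and 0.0476 as the adjusted p with an estimated correlation). TYMS stood at 1.83 ± 0.46 and MCM4 at 1.34 ± 0.30. Other TYMS probe sets gave 0.08 to 1.69. TYMS was not called without Auto animals 2, 3 or 4 (adjusted p = 0.0897, 0.256 and 0.125), MCM4 not without animals 3 or 4 (0.135 and 0.0754), and FDFT1 not without animals 1, 2 or 3 (0.0652, 0.0572 and 0.0702). None of 11 regulatory T cell genes passed, although the list was called (median 0.43, adjusted p = 5.75e-04, and 0.0476 as the adjusted p with an estimated correlation). The STAT5 feedback list had 1 of 17 members higher, or 5 adjusted over the list alone (median 0.26, adjusted p = 1.96e-04, and 0.0476 as the adjusted p with an estimated correlation). Activation and costimulation genes rose in 1 of 13, CD70 (1.81 ± 0.45, but an adjusted p of 0.125, 0.115 and 0.141 without Auto animals 1, 2 and 4), or 3 adjusted over the list alone (median 0.33, adjusted p = 9.42e-04, and adjusted p = 0.0888 with an estimated correlation). Glycolysis genes rose in 0 of 15, or 2 adjusted over the list alone (median 0.23, adjusted p = 0.0032, and adjusted p = 0.181 with an estimated correlation). CA6, a secreted carbonic anhydrase, had the highest fold (2.16 ± 0.47), and without Auto animal 1 it was not called (1.74, adjusted p = 0.108). MKI67 (0.99 ± 0.37), GZMB (0.36 ± 0.34), FOXP3 (0.43 ± 0.17) and IFNG (0.58 ± 0.59) did not pass. In all 56 genes were called, 51 higher and 5 lower, and 974 had an unadjusted p under 0.05. The 5 lower were ST3GAL5 (-1.18 ± 0.29), UNC45B (-1.05 ± 0.25), GGCT (-0.79 ± 0.20), ZG16 (-0.78 ± 0.20) and PNMA1 (-0.59 ± 0.15). Each of the 5 lost its call without at least 2 of the Auto animals, with an adjusted p from 0.0706 (UNC45B) to 0.320 (ZG16). The count was 33, 34 and 32 without Auto animals 2, 3 and 4, 122 within batch 9 alone, 19 on liver alone and 13 without a batch term.

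In lungs (4 Auto and 9 HC arrays) 7 of 18 p53 response genes rose, or 9 adjusted over the list alone (median 0.62, adjusted p = 6.81e-21, and 2.86e-05 as the adjusted p with an estimated correlation). DDB2 rose by 2.01 ± 0.15, MDM2 by 1.92 ± 0.30, ZMAT3 by 1.86 ± 0.25 and BAX by 1.81 ± 0.19, and within batch 9 DDB2 stood at 2.10 and BAX at 2.00. IL22 rose by 2.11 ± 0.45 and TYMS by 2.10 ± 0.46; without Auto animal 4 IL22 was not called (1.67, adjusted p = 0.0742), nor was it within batch 9 (2.50, adjusted p = 0.0922). TYMS had 3 probe sets, whose other folds lay between -0.07 and 1.74. PGC, a pepsinogen that lung epithelium also makes, had the highest fold (3.23 ± 0.42; 3.49 with adjusted p = 0.0810 within batch 9), and the collagen gene COL1A2 rose by 2.26 ± 0.44. Lung epithelial markers rose in 2 of 16 cases, SFTPD (1.58 ± 0.41) and CLDN18 (0.77 ± 0.18), or 5 adjusted over the list alone (median 0.26, adjusted p = 0.0052, and adjusted p = 0.762 with an estimated correlation). Without Auto animals 1 and 2 in turn the epithelial list had an adjusted p of 0.349 and 0.286, SFTPD 0.314 and 0.402, and CLDN18 0.202 and 0.277; within batch 9 that of the list was 0.144. The cell cycle list was called with 1 of 28 members higher, or 7 adjusted over the list alone (median 0.43, adjusted p = 6.49e-07, and adjusted p = 0.842 with an estimated correlation). Type I interferon genes rose in 1 of 28, TRIM22 (1.15 ± 0.22), or 2 with 1 that fell adjusted over the list alone (median 0.22, adjusted p = 0.0052, and adjusted p = 0.842 with an estimated correlation; adjusted p = 0.116 without Auto animal 3). None of 11 regulatory T cell genes passed over all genes and 1 did adjusted over the list alone (median 0.39, adjusted p = 0.0231, and adjusted p = 0.661 with an estimated correlation; adjusted p = 0.0651 and 0.0534 without Auto animals 2 and 3). MKI67 (0.75 ± 0.38), GZMB (0.28 ± 0.34) and IL17A (1.29 ± 0.51) did not pass. The comparison called 88 genes, 76 higher and 12 lower, 1190 had an unadjusted p under 0.05, batch 9 alone gave 202, and lungs alone gave 12.

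**Figure D3:**
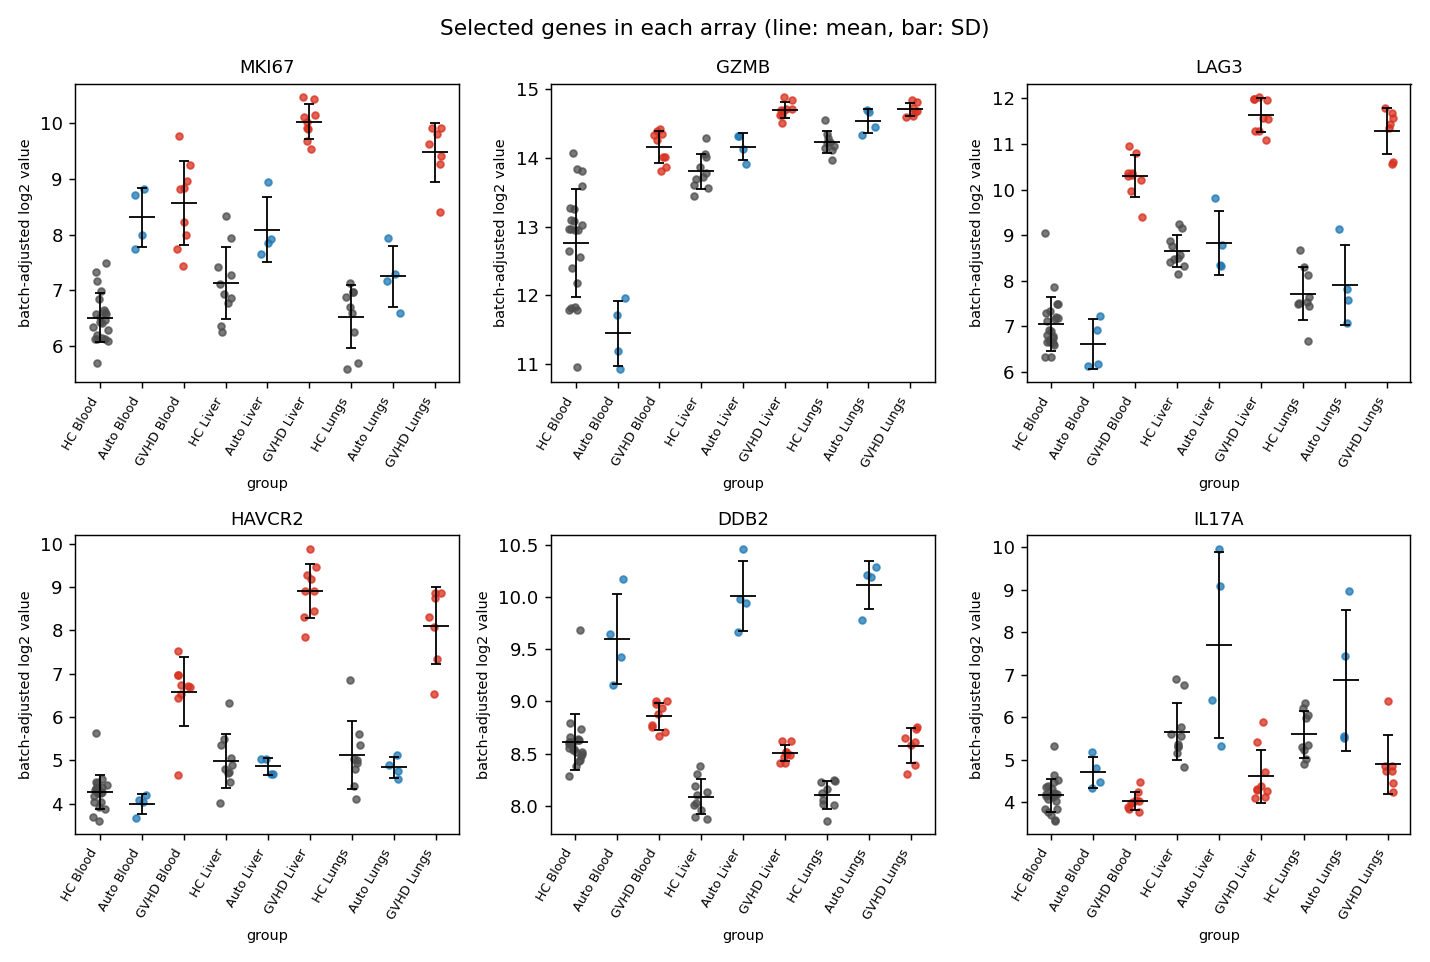
Batch-adjusted log2 values of 6 genes (vertical axis) in each array of the 9 groups (horizontal axis), with the group mean as a line and the SD as a bar. MKI67 averaged 6.51 in HC blood and 10.02 in GVHD liver, and DDB2 averaged 10.01 in Auto liver against 8.09 in HC liver.

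Set against the Auto arm, the GVHD arm asks what allogeneic transplantation adds to transplantation itself. No batch held blood arrays of both arms, so the blood comparison rests on other arrays that link the batches. These were HC arrays and GVHD liver and lung arrays, with batch shifts taken to be equal in all tissues. In blood (9 GVHD and 4 Auto arrays) GZMB was higher in GVHD by 2.74 ± 0.36, GNLY by 2.99 ± 0.34, IFNG by 2.45 ± 0.62, TBX21 by 1.66 ± 0.42, CXCR6 by 2.13 ± 0.50 and LAG3 by 3.69 ± 0.39. FOXP3 was lower, at -0.89 ± 0.18, and MKI67 did not pass (0.28 ± 0.40). The highest folds also included the chemokine receptor CCR3 (3.79 ± 0.57), IDO1, an enzyme of tryptophan breakdown (3.31 ± 0.93), LCN2 (3.11 ± 0.93) and LITAF (3.03 ± 0.52), and the lowest EYA4 (-2.82 ± 0.55), SOX4 (-2.45 ± 0.69), PHLDA1 (-2.26 ± 0.49) and HDAC9, a histone deacetylase (-2.15 ± 0.40). IDO1 was not called without Auto animal 2 (adjusted p = 0.0755) or 4 (0.0580), SOX4 without Auto animal 2 (0.0935) or 4 (0.0564), and LCN2 not without any single animal of the 4 (0.0627, 0.0670, 0.0812 and 0.0736). Other LCN2 probe sets had folds between -0.33 and -0.23, those of LITAF between 0.22 and 3.17, of SOX4 between -1.56 and 0.24, and of PHLDA1 between -1.26 and -0.04. The second probe sets of EYA4, HDAC9 and GNLY stood at -0.76, -0.01 and 1.69.

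Cytotoxic effector genes were higher in GVHD blood in 11 of 17 cases, also adjusted over the list alone (median 1.95, adjusted p = 8.61e-19, and 7.12e-04 as the adjusted p with an estimated correlation). NK cell markers moved with them, higher in 0 of 12, or 4 adjusted over the list alone (median 1.07, adjusted p = 0.0106, and adjusted p = 0.327 with an estimated correlation). Their mean was 7.28 in Auto blood (highest array 7.34) and 8.30 in GVHD blood (lowest array 7.59). Monocyte and macrophage markers were higher in 0 of 21, or 2 with 1 lower adjusted over the list alone (median 0.43, adjusted p = 0.0115, and adjusted p = 0.529 with an estimated correlation). Without the GVHD arrays high in neutrophil markers the monocyte list was not called (0.38, adjusted p = 0.108), the neutrophil median fell to 0.50 (adjusted p = 0.0099) and the erythroid and platelet median to 0.33 (adjusted p = 0.0163). The type 1 helper and interferon gamma axis had 5 of 10 members higher, or 7 adjusted over the list alone (median 0.93, adjusted p = 2.16e-07, and 0.0073 as the adjusted p with an estimated correlation). Tissue residency genes were higher in 3 of 16, or 8 adjusted over the list alone (median 0.76, adjusted p = 8.35e-05, and adjusted p = 0.0676 with an estimated correlation). Inhibitory receptor genes rose in 4 of 14 and fell in 1, or 5 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.0014, and adjusted p = 0.0806 with an estimated correlation). Naive and central memory genes fell in 4 of 13, or 5 adjusted over the list alone (median -0.45, adjusted p = 5.38e-05, and adjusted p = 0.0806 with an estimated correlation). P53 response genes fell in 4 of 18, or 5 adjusted over the list alone (median -0.42, adjusted p = 8.73e-04, and adjusted p = 0.157 with an estimated correlation). Neutrophil markers were higher in 3 of 10, or 7 adjusted over the list alone (median 1.98, adjusted p = 9.86e-07, and adjusted p = 0.139 with an estimated correlation). Erythroid and platelet markers were higher in 0 of 10, or 5 adjusted over the list alone (median 0.97, adjusted p = 2.62e-05, and adjusted p = 0.0894 with an estimated correlation). The comparison called 692 genes, 260 higher and 432 lower, with 116 and 103 at least 2-fold. The balance of the directions depended on the processing: quantile normalization gave 297 higher and 328 lower, and a fit on blood alone called 103 genes, 53 higher and 50 lower. Without Auto animals 2, 3 and 4 in turn the count was 386, 459 and 422, and without the GVHD arrays high in neutrophil markers 419.

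In liver (9 GVHD and 4 Auto arrays) ZBED2 (4.55 ± 0.68), CTHRC1 (4.29 ± 0.59), S100A9 (4.11 ± 1.21), HAVCR2 (4.07 ± 0.41), PLS3, an actin-bundling protein (4.0 ± 0.68), and S100A8 (3.95 ± 1.10) were highest in GVHD. SELENOP (-4.14 ± 0.91), ADAM12 (-3.58 ± 0.45), ZBTB16 (-3.48 ± 0.48), SLC40A1 (-3.48 ± 0.59) and MATN2 (-3.43 ± 0.50) were lowest. Other probe sets gave -1.94 and -1.57 for ADAM12 and 0.81 for PLS3. MKI67 (1.96 ± 0.39) was higher and IL17A (-3.09 ± 0.53) and TCF7 (-1.76 ± 0.34) lower. GZMB (0.52 ± 0.35), IFNG (-0.06 ± 0.61) and FOXP3 (-0.36 ± 0.18) did not pass. IL17A averaged 7.69 in Auto liver and 4.60, under the median probe set level, in GVHD, so its fold depends on background. Without Auto animal 2 it was -2.34 and without animal 3 -3.88. Of 18 p53 response genes 12 were lower, or 14 adjusted over the list alone (median -1.27, adjusted p = 3.25e-10, and 0.0128 as the adjusted p with an estimated correlation). Cell cycle genes were higher in 25 of 28 and lower in 1, also adjusted over the list alone (median 1.82, adjusted p = 1.28e-16, and adjusted p = 0.123 with an estimated correlation). Type 17 and type 22 helper genes were lower in 6 of 11 and higher in 2, or 6 and 3 adjusted over the list alone (median -1.49, adjusted p = 0.0059, and adjusted p = 0.156 with an estimated correlation). CCR6 stood at -2.12 ± 0.28 and IL23R at -2.10 ± 0.36. Tissue residency genes were lower in 4 of 16, also adjusted over the list alone (median -0.58, adjusted p = 0.0105, and adjusted p = 0.156 with an estimated correlation). Immediate early (Auto 10.22, GVHD 9.05) and NK marker means (10.14, 9.36) fell. T cell receptor signalling genes were lower in 4 of 15, or 5 adjusted over the list alone (median -0.23, adjusted p = 0.0185, and adjusted p = 0.156 with an estimated correlation). The comparison called 3233 genes, 1911 higher and 1322 lower, with 434 and 330 at least 2-fold. Batch 9 held 1 GVHD liver array, so it shows no spread of GVHD animals. IL17A stood at -2.99 there, the type 17 list at a median of -1.39 and the residency list at -0.35.

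In lungs (7 GVHD and 4 Auto arrays) LAG3 (3.40 ± 0.38), HAVCR2 (3.36 ± 0.41), CTHRC1 (3.33 ± 0.60), MKI67 (2.24 ± 0.39) and CD8B (1.0 ± 0.30) were higher in GVHD. The matrix genes LUM (-4.18 ± 0.51), COL1A2 (-4.06 ± 0.46) and COL11A1 (-3.35 ± 0.86) were lower, as were IL7, a survival cytokine of T cells (-3.12 ± 0.53), and IL17A (-1.99 ± 0.54). CD8B was not called without Auto animal 1 (0.54, adjusted p = 0.205), and IL17A not without Auto animal 2 (-1.30, adjusted p = 0.0612). IL7 had a second probe set at 0.03, and others gave -4.03 and -0.53 for LUM, -2.36 for COL1A2, and 1.34 and 1.85 for MKI67. IL17A averaged 6.87 in Auto and 4.89 in GVHD lungs. Of 18 p53 response genes 10 were lower and 1 higher, or 11 and 1 adjusted over the list alone (median -1.12, adjusted p = 8.66e-09, and 0.0348 as the adjusted p with an estimated correlation). Cell cycle genes were higher in 25 of 28, or 25 with 1 lower adjusted over the list alone (median 1.69, adjusted p = 2.88e-17, and adjusted p = 0.137 with an estimated correlation). Inhibitory receptor genes were higher in 6 of 14, or 6 with 1 lower adjusted over the list alone (median 0.71, adjusted p = 0.0011, and adjusted p = 0.0938 with an estimated correlation). Tissue egress and recirculation genes were lower in 3 of 7, or 5 adjusted over the list alone (median -0.76, adjusted p = 0.0150, and adjusted p = 0.196 with an estimated correlation). Plasma cell markers were higher in 4 of 8, also adjusted over the list alone (median 0.31, adjusted p = 0.0112, and adjusted p = 0.196 with an estimated correlation): MZB1 (2.19 ± 0.38), IRF4 (1.26 ± 0.31), FKBP11 (0.77 ± 0.12) and SDC1 (0.34 ± 0.12). T cells too express IRF4, and the mean fold of SDC1 over its probe sets was -0.01. Without Auto animals 1, 2 or 3 SDC1 was not called (adjusted p = 0.0665, 0.117 and 0.0507). Lung epithelial markers were lower in 5 of 16 and higher in 1, or 6 and 1 adjusted over the list alone (median -0.70, adjusted p = 0.0452, and adjusted p = 0.530 with an estimated correlation; adjusted p = 0.324 and 0.289 without Auto animals 1 and 2). The comparison called 2695 genes, 1350 higher and 1345 lower, with 291 and 333 at least 2-fold. Batch 9 (1 GVHD array, so no spread of GVHD animals) gave an epithelial median of -0.57, IL17A at -2.63 and CD8B at 0.95.

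The HC arm gives the baseline difference between T cells of an organ and of blood. In HC liver against blood (10 and 22 informative arrays) the chemokine genes XCL1 (4.59 ± 0.29) and CCL3 (4.45 ± 0.37), FASLG (4.16 ± 0.26), IFNG (4.15 ± 0.30) and CD160 (3.96 ± 0.32) were highest. The platelet chemokines PPBP (-4.80 ± 0.58) and PF4 (-4.41 ± 0.58), DACT1 (-4.30 ± 0.25) and RASGRF2 (-3.70 ± 0.20) were lowest. Other probe sets gave -0.49 for RASGRF2 and -3.10 and -1.79 for PF4. CCR7 was lower, at -3.37 ± 0.21, CXCR6 higher by 2.68 ± 0.24, CD69 by 1.18 ± 0.15, IL17A by 1.48 ± 0.26 and GZMB by 1.05 ± 0.17, and CD4 lower, at -0.86 ± 0.12 against a rise of 0.61 ± 0.07 in CD8A. Of 16 tissue residency genes 15 were higher and 1 lower, also adjusted over the list alone (median 1.78, adjusted p = 5.0e-11, and 5.13e-04 as the adjusted p with an estimated correlation). The type 1 axis was higher in 9 of 10, also adjusted over the list alone (median 1.63, adjusted p = 2.17e-08, and 0.0041 as the adjusted p with an estimated correlation). Immediate early genes were higher in 12 of 14, also adjusted over the list alone (median 1.47, adjusted p = 8.34e-10, and 0.0301 as the adjusted p with an estimated correlation). Naive and central memory genes were lower in 10 of 13, also adjusted over the list alone (median -0.96, adjusted p = 2.07e-08, and 0.0092 as the adjusted p with an estimated correlation).

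NK cell markers were higher in HC liver in 11 of 12 cases, also adjusted over the list alone (median 2.29, adjusted p = 2.41e-07, and 0.0303 as the adjusted p with an estimated correlation), in the same arrays in which the cytotoxic list was higher in 11 of 17 and lower in 2, also adjusted over the list alone (median 1.08, adjusted p = 1.99e-05, and adjusted p = 0.0852 with an estimated correlation). Hepatocyte markers were higher in 10 of 18, also adjusted over the list alone (median 0.27, adjusted p = 0.0046, and adjusted p = 0.238 with an estimated correlation). Monocyte and macrophage markers were higher in 13 of 21 and lower in 2, or 14 and 2 adjusted over the list alone (median 0.92, adjusted p = 0.0156, and adjusted p = 0.495 with an estimated correlation). Within batch 9 (2 arrays of each tissue) the median of the macrophage list was -0.46 (adjusted p = 0.0692), and CD74 stood at -0.20 against a pooled 1.20 ± 0.22. GZMB (1.36, adjusted p = 0.108) and IL17A (1.62, adjusted p = 0.324) were not called within it. In all 5761 genes were called, 2877 higher and 2884 lower in liver, with 444 and 240 at least 2-fold. Batch 7 alone (4 liver and 12 blood arrays) gave 4675, batch 8 alone (3 of each) 1055 and batch 9 alone 1773.

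In HC lungs against blood (9 and 22 informative arrays) FABP4, which macrophages also make (6.55 ± 0.48), CHP2 (6.37 ± 0.38), the surfactant gene SFTPB (4.58 ± 0.33), IL1B (4.46 ± 0.48), the nuclear receptor gene NR4A2 (4.42 ± 0.38) and PTX3 (4.08 ± 0.57) were highest, and PPBP (-4.61 ± 0.61), PF4 (-4.42 ± 0.61) and CA6 (-3.44 ± 0.25) lowest. Probe sets disagreed for some of these, with others at 0.07 for CHP2, 2.98 for FABP4, 0.38 to 4.51 for NR4A2, and -2.87 and -1.79 for PF4. IFNG was higher by 2.91 ± 0.31, CXCR6 by 1.59 ± 0.25 and GZMB by 1.49 ± 0.18, and CCR7 lower, at -2.17 ± 0.22. ITGAE (0.11 ± 0.13), CD8B (-0.04 ± 0.15) and MKI67 (0.02 ± 0.20) did not pass. Residency genes were higher in 12 of 16 and lower in 2, also adjusted over the list alone (median 1.11, adjusted p = 4.36e-06, and 0.0378 as the adjusted p with an estimated correlation). Naive and central memory genes were lower in 10 of 13, also adjusted over the list alone (median -0.90, adjusted p = 6.62e-07, and 0.0378 as the adjusted p with an estimated correlation). The heat shock and unfolded protein response list was higher in 10 of 14 and lower in 1, or 10 and 2 adjusted over the list alone (median 0.52, adjusted p = 7.05e-06, and 0.0400 as the adjusted p with an estimated correlation). Immediate early genes were higher in 12 of 14, also adjusted over the list alone (median 1.06, adjusted p = 5.42e-07, and adjusted p = 0.0555 with an estimated correlation). Chemokine genes were higher in 10 of 13, or 11 adjusted over the list alone (median 1.67, adjusted p = 1.05e-05, and adjusted p = 0.0555 with an estimated correlation).

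Markers of lung and myeloid cells were higher in the same HC lung arrays. The epithelial list had 9 of 16 members higher and 1 lower, also adjusted over the list alone (median 0.57, adjusted p = 2.11e-04, and adjusted p = 0.119 with an estimated correlation). The monocyte and macrophage list had 16 of 21 higher and 2 lower, also adjusted over the list alone (median 1.48, adjusted p = 6.73e-04, and adjusted p = 0.361 with an estimated correlation). LYZ stood at 2.86 ± 0.65 and MARCO at 2.30 ± 0.36. In batch 9 alone its median was -0.03 (adjusted p = 0.531). Endothelial and stromal markers were higher in 5 of 13 and lower in 1, also adjusted over the list alone (median 0.13, adjusted p = 0.0327, and adjusted p = 0.264 with an estimated correlation). The comparison called 6535 genes, 2813 higher and 3722 lower in lungs, with 597 and 277 at least 2-fold; batches 7, 8 and 9 alone gave 5475, 783 and 2952.

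**Figure D4:**
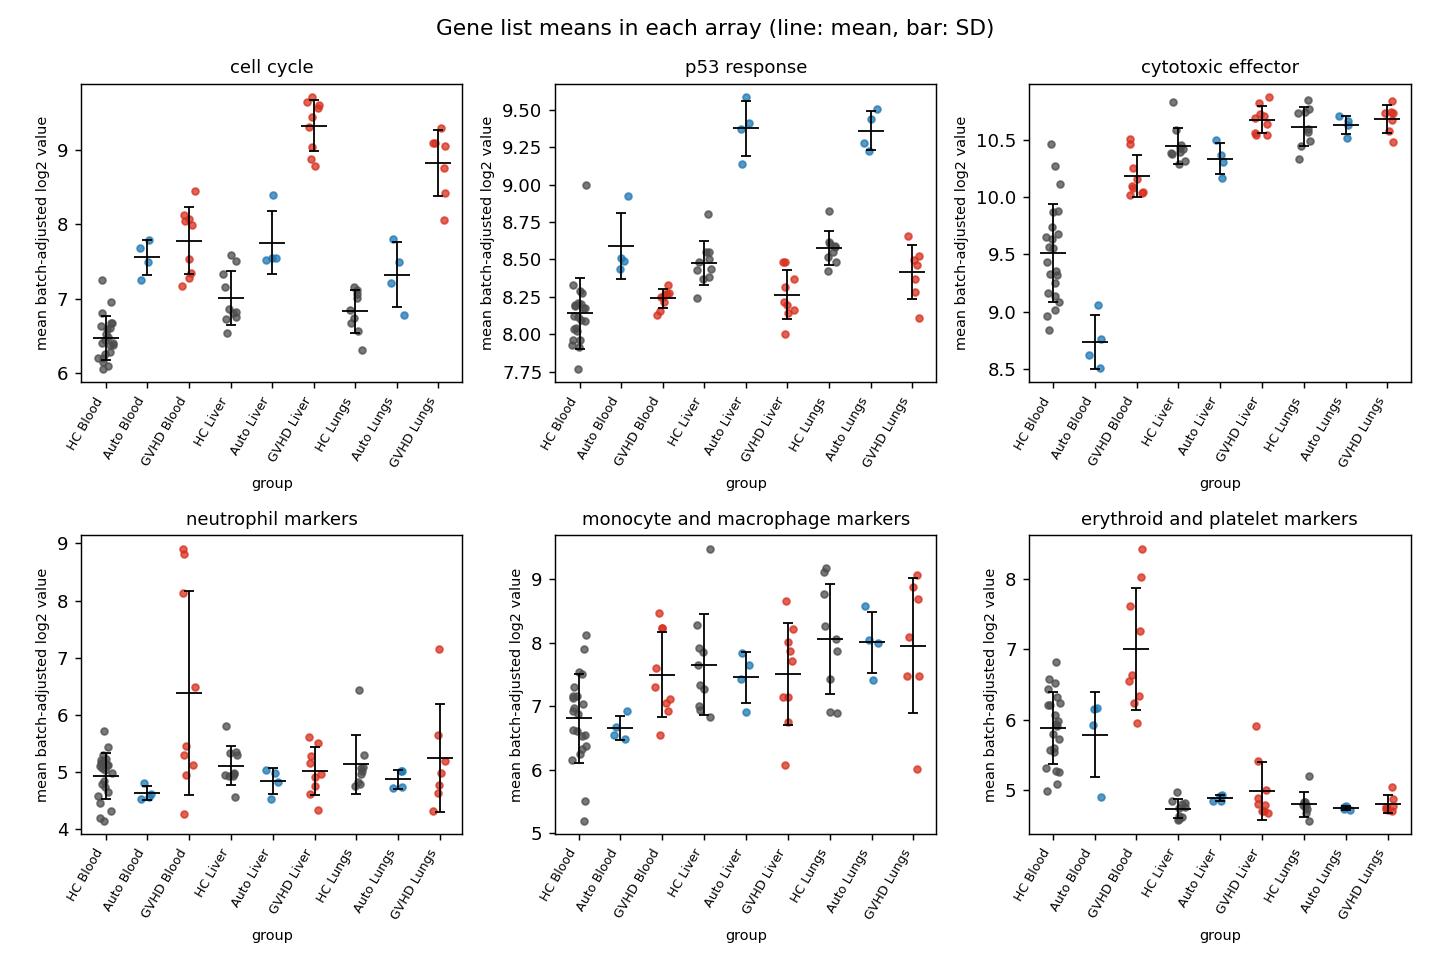
Mean batch-adjusted log2 value of 6 gene lists (vertical axis) in each array of the 9 groups (horizontal axis), with the group mean as a line and the SD as a bar. GVHD blood arrays 1, 4 and 6 lie at 8.13, 8.81 and 8.90 in neutrophil markers.

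A test of the difference itself showed where the GVHD effect in an organ departed from that in blood. For liver, the GVHD effect was greater than in blood for the receptor activator ligand gene TNFSF11 (3.03 ± 0.24), B3GNT5 (3.37 ± 0.40), EPYC (3.16 ± 0.31) and CTHRC1 (2.83 ± 0.44), and lower for CCL23 (-3.84 ± 0.51), STAP1 (-3.15 ± 0.41) and SLC40A1 (-3.12 ± 0.44). SLC40A1 fell in both tissues, and more in liver. The GVHD effect on MKI67 was greater in liver by 0.85 ± 0.29, and that on IFNG (-1.16 ± 0.45), TCF7 (-1.25 ± 0.25), CXCR6 (-1.30 ± 0.36) and ITGAE (-0.78 ± 0.19) lower. Other probe sets gave 0.48 for B3GNT5 and -1.18 and -0.56 for TCF7. Of 28 cell cycle genes 23 had a greater effect in liver, or 25 adjusted over the list alone (median 1.03, adjusted p = 4.71e-14, and adjusted p = 0.337 with an estimated correlation). The type I interferon list had 15 of 28 lower, or 18 adjusted over the list alone (median -0.49, adjusted p = 7.15e-05, and adjusted p = 0.388 with an estimated correlation). The residency list had 9 of 16 lower and 1 higher, also adjusted over the list alone (median -0.70, adjusted p = 0.0049, and adjusted p = 0.337 with an estimated correlation). The neutrophil list was lower in 9 of 10, also adjusted over the list alone (median -1.73, adjusted p = 4.76e-04, and adjusted p = 0.392 with an estimated correlation); without the GVHD arrays high in these markers its median was -0.25 (adjusted p = 0.519). In all 3268 genes differed, 1745 higher and 1523 lower, and 2204 did within batch 7, where MKI67 had an adjusted p of 0.0506.

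For lungs, the effect was greater than in blood for CCL2, a monocyte chemokine (2.96 ± 0.59), SPP1, which encodes osteopontin (2.32 ± 0.59), and PTCHD1 (2.27 ± 0.32), and lower for CCL23 (-3.59 ± 0.54), HBG2 (-3.55 ± 0.96) and PPBP (-2.93 ± 0.94). The effect on MKI67 was greater by 0.88 ± 0.31, and that on GZMB (-0.98 ± 0.28) and TBX21 (-0.97 ± 0.33) lower. In lungs GZMB stood at 13.98 to 14.56 in HC and 14.60 to 14.84 in GVHD, where the highest values of the GVHD lung arrays lay between 14.85 and 16.03. Whether a limit of the signal held its rise down was not tested. Cell cycle genes had a greater effect in lungs in 17 of 28 cases, or 23 with 1 lower adjusted over the list alone (median 0.81, adjusted p = 7.32e-09, and adjusted p = 0.498 with an estimated correlation). Cytotoxic genes had a lower one in 5 of 17, or 9 with 1 higher adjusted over the list alone (median -0.72, adjusted p = 2.52e-04, and adjusted p = 0.498 with an estimated correlation). The NK cell marker list moved the same way, with a median of -1.18. The neutrophil list was lower in 1 of 10, or 6 adjusted over the list alone (median -1.06, adjusted p = 0.0012, and adjusted p = 0.498 with an estimated correlation), and not called without the GVHD arrays high in these markers (-0.14, adjusted p = 0.366). The test called 1616 genes, 812 higher and 804 lower; 1196 were called within batch 7, where MKI67 (adjusted p = 0.166) and TBX21 (adjusted p = 0.0719) were not, and 799 without the GVHD arrays high in neutrophil markers.

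No comparison called the lists of type 2 helper genes, of chemokine receptors and integrins, or of B cell markers. In GVHD against HC blood the type 2 helper list had 1 of 10 members higher and 2 lower, or 0 and 1 adjusted over the list alone (median 0.02, adjusted p = 0.744). The chemokine receptor and integrin list had 8 of 19 higher and 4 lower, or 9 and 5 adjusted over the list alone (median 0.20, adjusted p = 0.412), and the B cell list 2 of 10 higher and 3 lower, also adjusted over the list alone (median -0.06, adjusted p = 0.644).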

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

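The tests of dissociation stress and of neutrophil-lineage cells on S100A8 and S100A9 were chosen after their results were seen; the macrophage test and the count without neutrophil-high arrays were chosen after the patterns were seen but before their own results; the single-batch fits used here and the splits were set before the data were seen.

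The higher neutrophil markers in GVHD blood were weighed first. Batch is argued against, since within batch 7 alone the list had a median of 1.99 (adjusted p = 3.63e-04). Of 10 measured markers 9 were higher. Cells of the neutrophil lineage may be a source: S100A8 and S100A9, abundant in neutrophils and outside the list, rose by 3.59 and 3.61. But the sort kept only cells with CD3. Without GVHD blood arrays 1, 4, 6 and 7, chosen by this list, its median fell from 1.32 to 0.14, while S100A9 was still called. The monocyte list, which holds both genes, was not called (median 0.26, adjusted p = 0.538). Without the arrays high in neutrophil markers 4136 genes were called, 4016 of them among the 5079. Neutrophil-lineage cells in the others were not excluded.

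The p53 response list in Auto organs was weighed next. Batch is argued against, since within batch 9 the median was 0.75 (adjusted p = 1.17e-11) in liver and 0.63 (adjusted p = 2.08e-08) in lungs. Dissociation stress is argued against, since the immediate early list had a median of 0.010 (adjusted p = 0.956) in liver and -0.13 (adjusted p = 0.669) in lungs. A response of T cells to the transplant procedure in the Auto arm may be a hypothesis, but conditioning, the graft and the day of sampling cannot be separated in this design and were not tested.

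The tissue residency list in HC organs was weighed last. Dissociation stress and tissue cannot be told apart in either organ. The immediate early mean lay within the blood range in only 1 liver array and 0 lung arrays, against 9 liver and 9 lung arrays above it, which leaves too few to decide. Earlier versions of this test counted called members, 14 of 15 and 7 of 8 in liver and 11 of 15 and 4 of 8 in lungs, and were dropped after their results were seen because such counts restate the pattern. The macrophage test cannot decide. All organ residency means exceeded every blood array, so the 8 liver and 5 lung arrays within the blood range of macrophage markers had to. Tissue itself stays open as the biological explanation.

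Other splits argue against chance for each comparison of groups, least firmly in Auto against HC liver and lungs. Auto splits, unlike the Auto arrays, could span batches. The real counts and the highest of the other splits were 5079 and 1331 for GVHD against HC blood, 5927 and 3242 for liver, and 5158 and 3700 for lungs. For Auto against HC they were 1528 and 670 in blood, 56 and 162 in liver, and 88 and 91 in lungs. For GVHD against Auto they were 692 and 89, 3233 and 731, and 2695 and 1032, and for HC liver and lungs against blood 5761 and 2036, and 6535 and 2921. For the difference in GVHD effect they were 3268 and 2081 in liver, and 1616 and 301 in lungs. Splits mixing GVHD and HC cannot test this difference. Of 100 splits 1, the real one, gave as many genes, except in Auto against HC liver (2) and lungs (3). The split that called 162 genes set Auto liver 2 and 4 with HC liver 3 and 9 against the others. What these arrays share was not tested.

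A difference between tissues in the GVHD effect was found in 3268 genes for liver and 1616 for lungs. Relative to blood, the median effect in liver was 1.03 for cell cycle, 0.17 for glycolysis and 0.19 for oxidative phosphorylation genes. It was -0.69 for the type 1 axis, -0.70 for residency, -0.49 for type I interferon, -0.30 for interferon gamma and -0.91 for immediate early genes. Among marker lists it was -1.13 for NK cells, -0.87 for macrophages, -1.73 for neutrophils and -0.51 for erythroid cells and platelets. Single genes that differed in liver were IFNG (-1.16), MKI67 (0.85), TCF7 (-1.25), ITGAE (-0.78) and CXCR6 (-1.30). In lungs the medians were 0.81 for cell cycle, 0.14 for oxidative phosphorylation, -0.72 for cytotoxic and -0.47 for immediate early genes. Marker lists had -1.18 for NK cells, -0.65 for macrophages, -1.06 for neutrophils, -0.17 for endothelium and stroma, and -0.83 for erythroid cells and platelets. Without the neutrophil-high arrays the neutrophil medians were -0.25 in liver and -0.14 in lungs, the erythroid and platelet medians -0.15 and -0.31, and none of these was called. MKI67 (0.88) and TBX21 (-0.97) differed in lungs, as did GZMB (-0.98), whose level in lungs was high, and a limit of the signal was not tested. With an estimated correlation none of these lists was called.

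In the groups other than HC blood, which was not tested, single arrays lay far from the others in 12 of 176 group values. Chance gives about 1 in 20. The 12 values were CD4 in HC liver 1 (7.56), CD8A in Auto lungs 1 (12.98), and CD8B in HC lungs 8 (9.79), Auto lungs 1 (9.48) and GVHD lungs 2 (10.94), with those below. TBX21 in Auto lungs 3 (11.53) and IL17A in GVHD lungs 2 (6.38) were others. Among list means they were cell cycle in Auto liver 3 (8.39), p53 response in HC lungs 2 (8.83) and Auto blood 1 (8.92), and neutrophil (6.43) and erythroid and platelet markers (5.2) in HC lungs 2.

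Probe sets without a gene symbol, which no comparison of the report used, differed between GVHD and HC in 4737 of 23775 cases in blood, 5106 in liver and 4261 in lungs.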

How the results depend on the processing

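Alternatives chosen after the data were seen were the fit without neutrophil-high GVHD arrays, the animal as a fixed term, the fit without batch 10, the fit without the HC animal whose probe sets oppose its sex label, and the single batches for tissue and interaction comparisons. Quantile normalization, the trend and robust prior, the sex covariate and the mean over probe sets kept all 13 counts within 1.5 times, and of 804 named gene results 785, 795, 794 and 773 kept direction and side of the threshold. Batch 7 alone kept 433 of 473, no batch term 727 and the title-number block 665 of 804, batch 9 alone 317 of 444 and single tissues 379 of 515. Of 156 called lists 137 lost their call with an estimated correlation. The dim filter left 694 named gene results. In the counts below the cause was not tested except where fewer arrays or genes are the construction.

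Without a batch term Auto against HC called 2294 genes in blood and 13 in liver, and GVHD against Auto blood 1044; the p53 list then turned in camera's direction in Auto against HC blood (median 0.20, adjusted p = 0.938) and in GVHD against Auto blood (0.047, adjusted p = 0.2). With the animal ignored (no replicate block) Auto against HC lungs called 161 and the lung interaction 1017, and with the title number as a replicate block Auto against HC liver called 17, lungs 53 and the lung interaction 698. With fewer arrays, single tissues gave 144, 19 and 12 for Auto against HC blood, liver and lungs, and 103 and 1310 for GVHD against Auto blood and lungs. Batch 9 alone gave 595, 122 and 202 for Auto against HC, 1188 for GVHD against Auto lungs, and 1773 and 2952 for HC liver and lungs against blood, for which batch 8 alone gave 1055 and 783. The dim filter gave 35 for Auto against HC lungs, GVHD arrays of day 8 gave 401 for GVHD against Auto blood, and leaving out animals in 2 arms 26 for Auto against HC liver. Without neutrophil-high GVHD arrays GVHD against Auto blood called 419 and the lung interaction 799. Without each Auto animal in turn, counts ranged from 992 to 1221 for Auto against HC blood, 32 to 60 for liver, and 386 to 479 for GVHD against Auto blood.

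The other reversals follow. In batch 9 alone HC liver against blood had CD74 at -0.20, CD8B at -0.29, LYZ at -1.89, MAMU-DRA at -0.77 and the macrophage list at -0.46, and lungs against blood CD74 at -0.16, IDO1 at -0.47, MAMU-DRA at -0.13 and the macrophage list at -0.033. In batch 8 alone FOXP3 stood at 0.18 in liver and CD4 at 0.0048 in lungs. As a mean over probe sets ATP5F1C stood at -0.16, NDUFB6 at -0.069 and RPS16 at 0.034 in GVHD against HC blood, RPS16 at 0.045 in liver and 0.13 in GVHD against Auto liver, and SDC1 at -0.0076 in GVHD against Auto lungs. Without neutrophil-high arrays TUBB1 stood at 0.15 in the liver interaction. The number of arrays limits the precision throughout.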

Other observations

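HC blood array 4 stood apart from the other HC blood arrays in several measures. Its batch-adjusted DDB2 level was 9.69, where the next highest was 8.79, its LAG3 level was 9.05 against 7.86, its HAVCR2 level 5.64 against 4.56, and its mean over the p53 response list 9.00 against 8.33. It was noticed after the values were seen.

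The reading of sex-separating probe sets and its tests were chosen after the result was seen. Among 23775 probe sets without a symbol, 46 differed by sex label, and 5 in each direction placed 68 arrays on a scale from female (0) to male (1). Of 43 HC and Auto arrays 42 lay on the side of their label, males from 0.98 and females up to 0.10. The exception was HC blood 7. Not read were the 8 arrays of batches 2, 5 and 10, among them GVHD blood 8, and 3 HC arrays whose batch held no other HC or Auto animal of that sex label. The remaining array of the 68, HC blood 2, belongs to the animal with conflicting sex labels, is labelled male and lay on the male side. Among 24 GVHD arrays of 9 animals, 14 arrays of 5 animals lay on the other side. The animal of GVHD blood 6, labelled female, lay from 0.96 to 0.99, and that of GVHD blood 9, with conflicting labels, from 0.77 to 0.94. Animals labelled male lay from 0.15 to 0.22 (GVHD blood 2), 0.13 to 0.35 (GVHD blood 3) and 0.14 to 0.23 (GVHD blood 5).

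For the 9 arrays of the 3 GVHD animals labelled male a candidate explanation is that the sorted T cells came largely from a donor of the other sex. In the Auto arm, where the cells are the animal's own, 0 of 12 arrays lay on the other side. Wrong sex labels alone are argued against for these animals, since 9 of the 9 arrays lay between the ranges of the control arrays. For the animal of GVHD blood 6 a wrong label would be enough: 1 of its 2 arrays lay between the ranges, at 0.96, and so did arrays of the animal of GVHD blood 4, which lay on the side of its label. For the animal with conflicting labels 3 of 3 arrays lay between the ranges, on the side of its own HC array, and a wrong label on them stays open too. The labels give no sex of any donor, so the hypothesis stays untested beyond these values.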
